A study of Mus musculus with 6 samples.

How the data were processed

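RNA from the epidermis of 6 mouse embryos was hybridised, per the labels after biotin labelling with the Ambion WT Expression kit, to one-colour whole-transcript arrays. The sheets came from skin held in 3.8% ammonium thiocyanate for 10 minutes. The authors processed the arrays with RMA (background correction, quantile normalization and a summary per transcript cluster) in Partek, with build mm10 named for the annotation, and gave no versions or settings. The deposited values are on a log2 scale. The base of the logarithm is not stated and was inferred from RMA and from the range of the values, 1.25 to 13.91. The table holds 72688 probesets for 6 arrays, without detection calls, and no raw intensities were used.

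Each array was assigned to the group in its title, which the source name and the description repeat. For 2 arrays the genotype and strain characteristics state the other group, and the grouping by characteristic was run as an alternative. The strain characteristic divides the 6 arrays as the genotype characteristic does. Taken as a block, it therefore adjusts for the conflicting label and not for a separate strain background. Probesets were joined to gene symbols through the annotation table of the array: 30638 name 1 gene, 2176 name several and 39874 name none. Only those with 1 gene were tested. For the 354 genes with several probesets, the one with the highest mean over the 6 arrays was taken, which left 30176 genes. Positions are from RefSeq genes on mm10 for the 22210 genes matched by NCBI gene number.

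Rheb cKO was compared with wild type by limma (version 3.58.1 in R 4.3.3, with jsonlite 2.0.0 for the labels), with lmFit and eBayes on the deposited values, 3 arrays per group and no covariate. P-values were adjusted by Benjamini-Hochberg over the 30176 genes, and a gene passed at an adjusted p under 0.05. Errors given as SE are the moderated standard errors of the log2 change. No pseudocount or expression filter was applied. Rheb was also tested with an exact two-sided permutation test. A total of 36 gene lists and cell type marker lists were fixed before the data were examined, and 35 of them, with at least 5 measured members, were tested with camera at a preset correlation of 0.01 and adjusted over the 35. The sex-linked list was described and not tested. Of 773 distinct members 22 belong to more than 1 list. Camera with estimated correlations, fry and 10000 random lists matched on mean level were run beside it. Member counts are given over all genes and adjusted over the list alone.

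The genes named were chosen by a rule fixed before the data were examined. It took Rheb, the 12 largest rises and 12 largest falls among genes that passed, whose groups did not overlap and whose mean exceeded the median of all probesets (3.21), and up to 4 members of each list with the smallest p. It left out predicted and small RNA genes, and added 14 genes of adhesion, Rho, transforming growth factor beta and mTORC1 whatever their values, and the 5 sex-linked genes. Rock2 and Ddx3y have no probeset of their own and are not analysed here. Krt6a and Krt6b share 1, which was tested among all probesets and counted in no list. Genes named outside the rule are said to be.

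The alternatives were the grouping by characteristic, leaving out each array or both arrays with conflicting labels, the strain characteristic as a block, the Y-linked mean as a covariate, quantile normalization, centring on the array median, a filter on dim genes, all probesets, the mean of a gene's probesets, trend, robust and unmoderated variance models, array weights and other thresholds. After the data were seen, 3 more were added: linear rescaling of each array to equal medians of the 5222 negative and 1324 positive control probesets, centring on the positive controls, and the mean of the background controls with 16 to 25 G or C bases as a covariate. The number of arrays limits the precision. The steps were tested on simulated data with each gene's spread in these arrays: of 50 genes changed by a log2 value of 0.5, 1, 2 and 3, limma recovered 11, 36, 47 and 50, with 7 false calls among unchanged genes. Values were drawn independently for each gene and array, and only genes above the probeset median were changed. Differences that many genes of an array share were not simulated, so these rates do not cover them.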

Results

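Gene expression was measured in epidermal sheets of late mouse embryos in which the small GTPase Rheb, the direct activator of the protein kinase complex mTORC1, had been removed from keratinocytes, and in littermates that kept it. The mutants are called Rheb cKO (conditional knockout, made per the labels with a Cre recombinase under the keratin 14 promoter, which is active in the basal layer of the epidermis). The sheets had been freed from the dermis with ammonium thiocyanate. One-colour whole-transcript arrays were hybridised with 3 wild type samples (replicates 1, 2 and 3) and 3 Rheb cKO samples (replicates 4, 5 and 6), described as biological replicates. The protocol places the embryos at stage E18.5 (embryonic day) and the sample characteristics at E19.5, so the stage is known only to within these labels. The values are log2 intensities, and the number of arrays is what limits the precision. The series title ties the loss of mTORC1 to skin adhesion and to Rho kinase, so the genes of cell junctions and of the Rho pathway were among the lists fixed before the data were examined.

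Rheb was lower in every Rheb cKO array than in every wild type array. This gene (NCBI gene 19744) lies on mouse chromosome 5 from 24802823 to 24842361 in build mm10 and codes for protein. Its log2 level was 6.28, 6.04 and 5.93 in wild type replicates 1, 2 and 3, and 5.51, 5.51 and 5.66 in Rheb cKO replicates 4, 5 and 6. The means were 6.09 ± 0.18 and 5.56 ± 0.09 (SD, n = 3 each), a 1.44-fold lower level in the mutant (log2 change -0.52 ± 0.11 SE, limma adjusted p = 0.0283). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 arrays allow. The call was lost, with log2 changes between -0.60 and -0.50, when any array other than wild type replicate 1 was left out. The labels do not say which part of the gene was removed or where its probes lie, so a partial fall cannot be read as a partial knockout. For 2 arrays, Rheb cKO replicate 4 and wild type replicate 3, the genotype characteristic contradicts the title, the source name and the description. The groups follow the title, and grouped by the characteristic limma called 0 genes at an adjusted p under 0.05 (470 at an unadjusted p under 0.05).

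**Figure D1:**
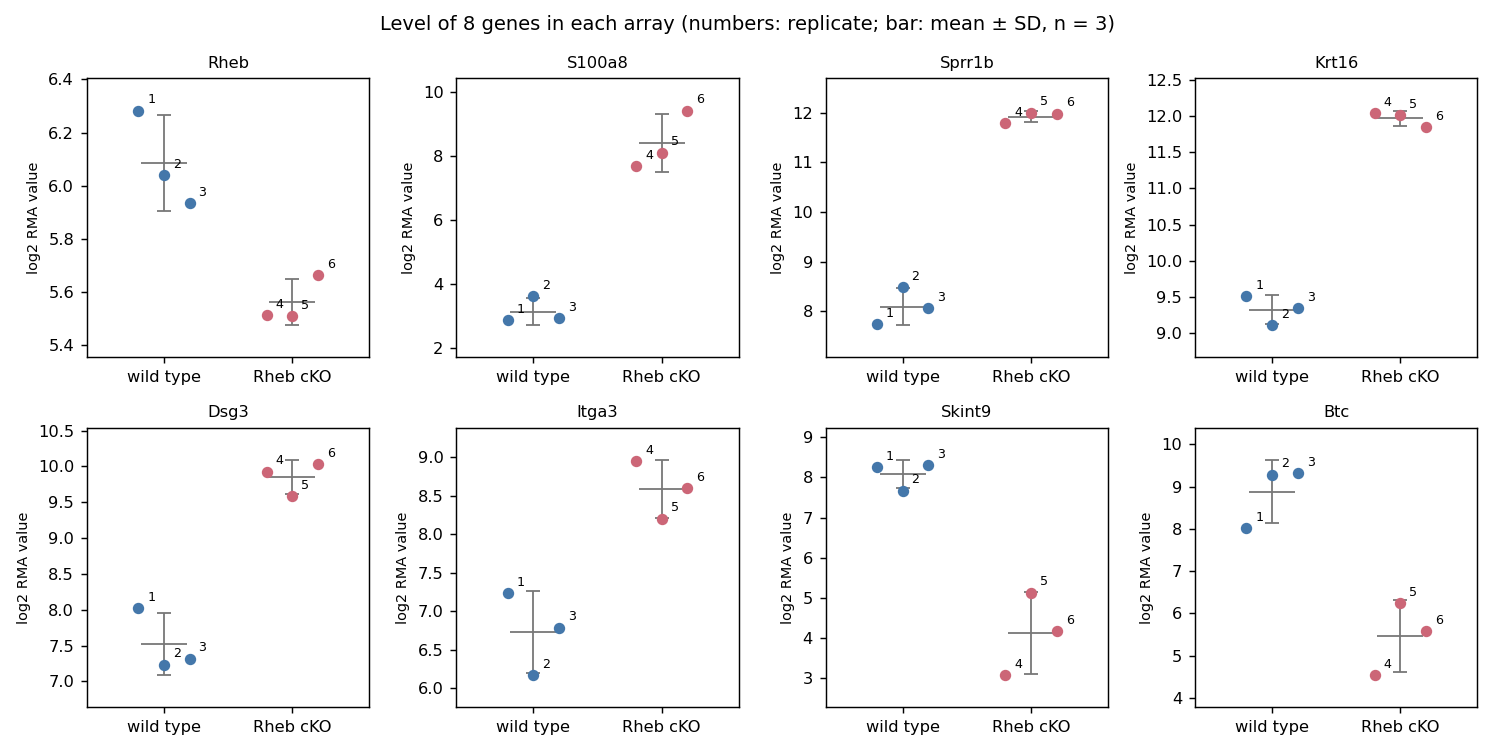
Log2 RMA values (y axes, each with its own range) of 8 genes in the 3 wild type and 3 Rheb cKO arrays (x axis); points are arrays numbered by replicate, and bars show the mean and SD. The groups do not overlap for any of the 8, with Rheb, Skint9 and Btc lower and the other 5 higher in Rheb cKO.

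The 12 largest rises in Rheb cKO were in 4 genes of secreted antimicrobial and alarm proteins and in 8 members of gene families of the cornified envelope, the protein shell of dead surface keratinocytes. S100a8 and S100a9, which encode the subunits of the alarmin calprotectin, were 38.5-fold and 34.1-fold higher in Rheb cKO (log2 changes 5.27 ± 0.44 and 5.09 ± 0.33 SE, limma adjusted p = 0.00347 and 0.00145, higher in 3 of 3 mutants than in any wild type array). Defb3, a beta-defensin, rose 17.7-fold, and S100a7a, another S100 protein of inflamed skin, rose 10.7-fold. The 8 were small proline-rich (Sprr) and late cornified envelope (Lce) genes, and the annotation calls 2 of them, Sprr2g and Sprr2j-ps, transcribed pseudogenes. Among them Sprr2f rose 21.4-fold, Lce3f 20.5-fold, Sprr1b 14.2-fold and Lce3d 13.3-fold, and Sprr2g, Sprr2j-ps, Lce3a and Sprr1a rose by between 9.93-fold and 16.9-fold. Related members of these families can share probe sequence, so the split of signal between them is uncertain. S100a8, Sprr2g and Lce3a had wild type means of 3.14, 3.12 and 3.10, below the median of all probesets at 3.21, so their folds are uncertain at the floor of the array. All 12 calls held when each array was left out in turn and under the 4 other scalings, but 10 held without both arrays with conflicting labels and 4 with the GC-rich background as a covariate.

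The 12 largest falls were in genes of several kinds. Skint9, of the Skint family whose founding member is needed for the skin's resident T cells, was 15.4-fold lower in Rheb cKO (wild type 8.08 ± 0.35, Rheb cKO 4.13 ± 1.02, SD, limma adjusted p = 0.00848). Slc46a2, a solute carrier, was 11.6-fold lower, and Btc, which encodes the epidermal growth factor receptor ligand betacellulin, was 10.7-fold lower. Unc93a2 fell 9.01-fold, Dapl1 8.16-fold, Slurp2 7.41-fold, Serpinb3c, a protease inhibitor gene, 7.26-fold, and Oas1f, of the oligoadenylate synthetase family, 7.14-fold. The remaining 4 of the 12 encode enzymes. Hsd17b2, which inactivates sex steroids, fell 8.54-fold, Npl, of sialic acid breakdown, 8.14-fold, Adh1, an alcohol dehydrogenase, 6.64-fold, and Bbox1, of carnitine synthesis, 6.54-fold. Of these 12 calls, 4 (Skint9, Npl, Oas1f and Bbox1) held without each array in turn. Leaving out wild type replicate 3 ended the other 8, and every one of the 12 kept its call under the 4 other scalings, but 5 did without both arrays with conflicting labels and 0 with the GC-rich background as a covariate.

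Across 30176 genes, 1935 were higher and 953 lower in Rheb cKO at a limma adjusted p under 0.05, together 9.57% of the genes tested, and 292 and 239 of them by 2-fold or more. At an unadjusted p under 0.05 there were 7739 genes, the base against which unadjusted counts within lists should be read. The arrays of the groups did not overlap for 31.1% of genes. For a single gene without a group difference 10% is expected. Genes of an array can shift together and the share was not computed for other splits, so this comparison is no test against chance. The call count rested strongly on single arrays: it was 290 higher and 127 lower without Rheb cKO replicate 6, 341 and 142 without wild type replicate 3, 649 and 280 without Rheb cKO replicate 4, 814 and 406 without wild type replicate 2, 1405 and 532 without Rheb cKO replicate 5, and 3207 and 1706 without wild type replicate 1. Without the 2 arrays whose labels disagree, 44 genes were higher and 10 lower. The balance of rises and falls depended on the scaling: 67% of calls were rises in the deposited values, 74.3% with each array centred on its median, 59.6% after quantile normalization, 28.6% after rescaling to the control probesets and 10.6% after centring on the positive controls. The last 2 scalings moved the median log2 change of all genes from -0.04 to -0.16 and -0.32, so list medians are also given relative to all genes. Under both, falls outnumbered rises in the mTORC1, suprabasal, glycolysis and oxidative phosphorylation lists, where rises lead in the deposited values.

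Stress keratins and alarmins, genes that the epidermis switches on in wounds and inflammation, were tested as a list. Of 24 measured members, 13 rose, 0 fell and 11 did not pass the test. Adjusted over the list alone, 14 rose and 1 fell. Krt16, a wound keratin, was 6.27-fold higher (log2 change 2.65 ± 0.12 SE, limma adjusted p = 0.000395), and Hbegf, a growth factor of wound edges, 3.89-fold higher. S100a9 and S100a7a were the others of the 4 members with the smallest p, and S100a8 and Krt17 also belong to the list. The probeset that Krt6a and Krt6b share, outside the gene test, rose from 9.40 to 12.46 (log2 change 3.06 ± 0.22 SE, limma adjusted p = 0.00914 over all probesets). The list median was 0.80 (camera adjusted p = 7.23e-11 with the preset correlation). With an estimated correlation the call was lost (adjusted p = 0.480), while fry, which tests a shift of the list on its own, gave an adjusted p of 0.0131. Between 10 and 14 members rose when single arrays were left out, fewest without Rheb cKO replicate 6 or wild type replicate 3. Relative to all genes the median was 0.84, 0.78 after quantile normalization and 0.73 after rescaling to the control probesets.

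The cornified envelope and granular layer list split by gene family. Of 48 measured members 12 rose, 2 fell and 34 did not pass, and adjusted over the list alone 15 rose and 10 fell. All 12 that rose were Sprr genes, Lce3 genes or Rptn (repetin), with Sprr1b, Sprr1a, Sprr2e and Sprr2f at the smallest p. The 2 that fell, named after their values were seen, were Casp14 (log2 change -2.20 ± 0.45 SE), a caspase that processes filaggrin, and Padi1 (-1.43 ± 0.20 SE), which citrullinates proteins in differentiating keratinocytes. The median of the list was -0.41, its mean 0.30, and the list did not pass with camera (adjusted p = 0.764, or 0.944 with an estimated correlation). Camera called it higher grouped by characteristic, with the GC-rich background covariate and after centring on the positive controls, where 13 members rose, 24 fell and the median was -0.69, and its median was lower than in random lists. The families occupy neighbouring stretches of the epidermal differentiation complex on chromosome 3 (mm10). There the 13 Lce1 genes had a median log2 change of -1.19 with 0 past the threshold (10 at an unadjusted p under 0.05), against 2.79 for the 6 Lce3 genes (4 rose) and 2.82 for the 13 Sprr genes (11 rose). Families were chosen for this count after their values were seen.

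**Figure D2:**
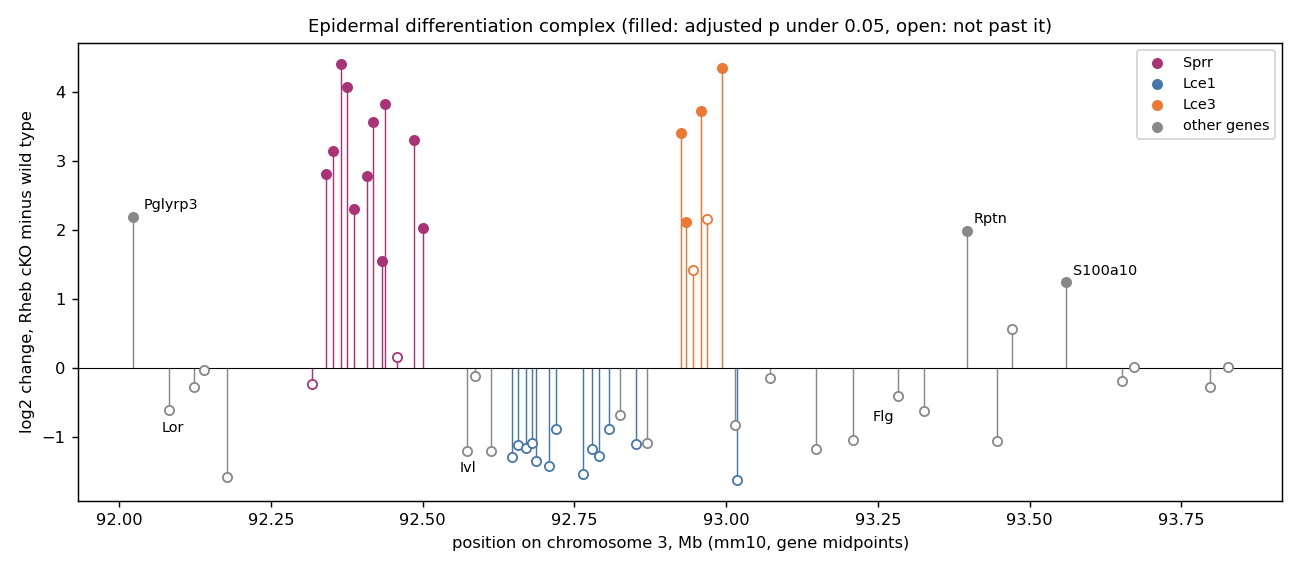
Log2 change, Rheb cKO minus wild type (y axis), of each measured gene against its midpoint on chromosome 3 in Mb (x axis, mm10); each line is a gene, filled points passed the limma threshold and open points did not. The 11 filled Sprr genes and 4 filled Lce3 genes lie above 0, and all 13 Lce1 genes lie below 0 with open points.

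Other differentiation lists changed in few members. Of 19 suprabasal genes 3 rose and 0 fell: Sfn, which encodes the stratifin adaptor (log2 change 1.38 ± 0.10 SE), the receptor gene Notch1 (1.05 ± 0.22 SE) and the transcription factor gene Grhl3 (1.04 ± 0.26 SE). Krt10, a keratin of these layers, was at 12.23 in wild type and 11.84 in Rheb cKO and did not pass (limma adjusted p = 0.0811). Of 17 genes of corneodesmosomes and desquamation, the shedding of surface cells, 2 rose and 1 fell. The kallikrein protease genes Klk10 (2.74 ± 0.25 SE) and Klk6 (1.88 ± 0.35 SE) rose and Lgmn, a lysosomal protease gene, fell (-0.45 ± 0.10 SE), while Klk5 did not pass (-1.04 ± 0.41 SE). Adjusted over the list alone, 6 rose and 3 fell among the suprabasal genes and 2 rose and 1 fell among the desquamation genes. Neither list passed with camera (adjusted p = 0.195 and 0.206), but the suprabasal list passed as higher against other genes after centring on the positive controls, where 2 members rose and 7 fell, and the desquamation list as lower with the strain characteristic as a block and without wild type replicate 1 and as higher grouped by characteristic and with the GC-rich background covariate. The calls of Notch1, Grhl3 and Lgmn were lost when any array other than wild type replicate 1 was left out, and that of Klk6 without Rheb cKO replicate 5, Rheb cKO replicate 6 or wild type replicate 3. The median of the suprabasal list was 0.19 relative to all genes and turned negative after rescaling to the control probesets (-0.04) and after quantile normalization.

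Adhesion genes were examined by junction type. Of 16 desmosome genes 5 rose, 0 fell and 11 did not pass, and 10 rose over the list alone. Dsg3, the cadherin of the basal desmosome and the pemphigus antigen, was 5.01-fold higher (7.52 ± 0.43 in wild type, 9.85 ± 0.24 in Rheb cKO, SD, limma adjusted p = 0.00457). The plakophilin genes Pkp3 (log2 change 0.79 ± 0.07 SE) and Pkp4 (1.14 ± 0.23 SE) and the plakoglobin gene Jup (0.46 ± 0.09 SE) also rose. Pkp1, the fifth to rise and named after its values were seen, changed by 0.61 ± 0.14 SE. Dsg1a, a cadherin of the upper layers, was at 10.02 in wild type and 10.00 in Rheb cKO, and Dsp, the desmoplakin gene, was at 11.16 and 11.63 (limma adjusted p = 0.930 and 0.0510). Members of the list had a median of 0.47 (camera adjusted p = 1.20e-05, adjusted p = 0.480 with an estimated correlation), which was 0.05 after rescaling to the control probesets (0.21 relative to all genes). Between 2 and 8 members rose when single arrays were left out, fewest without Rheb cKO replicate 4, Rheb cKO replicate 6 or wild type replicate 3. The calls of Dsg3 and Pkp3 held in all of these fits.

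Other junction lists were smaller or mixed. Of 12 adherens junction genes 3 rose and 0 fell (5 and 2 over the list alone): Nectin1, a cell adhesion receptor gene (log2 change 1.26 ± 0.21 SE), Ctnna1, the alpha-catenin gene (0.87 ± 0.14 SE), and Vcl, the vinculin gene (0.56 ± 0.13 SE). Cdh3, the P-cadherin gene (0.84 ± 0.23 SE), and Cdh1, the E-cadherin gene (0.56 ± 0.18 SE), did not pass. The list passed narrowly (camera adjusted p = 0.0320, adjusted p = 0.480 with an estimated correlation), and 0 of its genes passed without Rheb cKO replicate 4, Rheb cKO replicate 6 or wild type replicate 3. The list call was lost without Rheb cKO replicate 6, after quantile normalization or median centring, with dim genes left out, grouped by characteristic and with the GC-rich background covariate, and its median of 0.36 was 0.06 after control rescaling (0.22 relative to all genes). Of 18 tight junction genes 1 rose and 3 fell, as over the list alone. Tjp3 (-1.31 ± 0.17 SE) and Cgn (-1.34 ± 0.30 SE), which encode scaffold proteins, and Ocln, the occludin gene (-0.65 ± 0.16 SE), fell, and F11r, which encodes a junctional adhesion molecule, rose (0.41 ± 0.08 SE). This list did not pass (camera adjusted p = 0.0862), but it passed as lower with the strain characteristic as a block, after quantile normalization, median centring or control rescaling, and without Rheb cKO replicate 5. The calls of Vcl, Ocln and F11r were lost when any array other than wild type replicate 1 was left out, and that of Tjp3 without Rheb cKO replicate 6 or wild type replicate 3, which with wild type replicate 2 also carried that of Cgn.

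Basal keratinocyte and hemidesmosome genes, whose products anchor the basal layer to the basement membrane, were tested next. Of 16 measured, 8 rose and 0 fell, and 12 rose and 1 fell over the list alone. The integrin genes Itga3 (log2 change 1.85 ± 0.29 SE) and Itgb1 (1.41 ± 0.19 SE), the tetraspanin gene Cd151 (0.94 ± 0.14 SE) and the basal keratin gene Krt14 (1.49 ± 0.25 SE) had the smallest p. Krt15, another basal keratin gene, named after its values were seen, went the other way without passing (-1.09 ± 0.30 SE, limma adjusted p = 0.0691). The list median was 0.84 (camera adjusted p = 2.64e-06, adjusted p = 0.596 with an estimated correlation), and relative to all genes it was 0.88, 0.75 after quantile normalization and 0.71 after control rescaling. The list did not pass with the GC-rich background covariate or grouped by characteristic. Without wild type replicate 3, 0 of the 16 rose.

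Genes of the Rho and actomyosin list, which builds and contracts the actin cytoskeleton, rose more often than they fell. Of 42 measured, 15 rose and 1 fell, and 20 rose and 1 fell over the list alone. Tpm2, a tropomyosin gene (log2 change 1.18 ± 0.14 SE), the small GTPase gene Rhob (1.04 ± 0.12 SE), Cfl1, the cofilin gene (0.76 ± 0.09 SE), and Ezr, the ezrin gene (0.74 ± 0.09 SE), had the smallest p. Rhoa rose 1.35-fold (limma adjusted p = 0.0163), and its call was lost under 3 of the 4 other scalings. Rock1, the gene of a Rho kinase, was 1.79-fold higher without passing the test (6.09 ± 0.58 against 6.93 ± 0.36, SD, limma adjusted p = 0.133), and Rock2 was not analysed here because no probeset names it alone. The gene that fell, named after its values were seen, was Rnd1 (-0.57 ± 0.14 SE), an atypical Rho GTPase. Members of the list had a median of 0.34 (camera adjusted p = 9.50e-06, adjusted p = 0.480 with an estimated correlation), which was 0.08 after control rescaling (0.24 relative to all genes), and the list did not pass grouped by characteristic. Without Rheb cKO replicate 6, 4 members rose.

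Of 33 genes of transforming growth factor beta signalling, 7 rose and 0 fell, and 14 rose and 3 fell over the list alone. Ccn1, a matricellular protein gene, was 3.78-fold higher (log2 change 1.92 ± 0.23 SE). Itgb6, of the integrin that activates the latent ligand (1.05 ± 0.14 SE), the signal transducer gene Smad3 (1.01 ± 0.16 SE) and the target gene Pmepa1 (0.52 ± 0.08 SE) also rose. The ligand gene Tgfb1 rose 1.69-fold (limma adjusted p = 0.0245). Tgfb2 (-0.11 ± 0.12 SE), Tgfb3 (-0.33 ± 0.14 SE) and the receptor gene Tgfbr1 (0.49 ± 0.19 SE) did not pass. The list median was 0.29 (camera adjusted p = 0.00183, adjusted p = 0.508 with an estimated correlation), and 2 members rose without Rheb cKO replicate 6 or wild type replicate 3. The median was 0.06 after control rescaling (0.22 relative to all genes), and the list did not pass with the GC-rich background covariate or grouped by characteristic. The call of Tgfb1 was lost without wild type replicate 2, Rheb cKO replicate 4, Rheb cKO replicate 6 or wild type replicate 3.

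**Figure D3:**
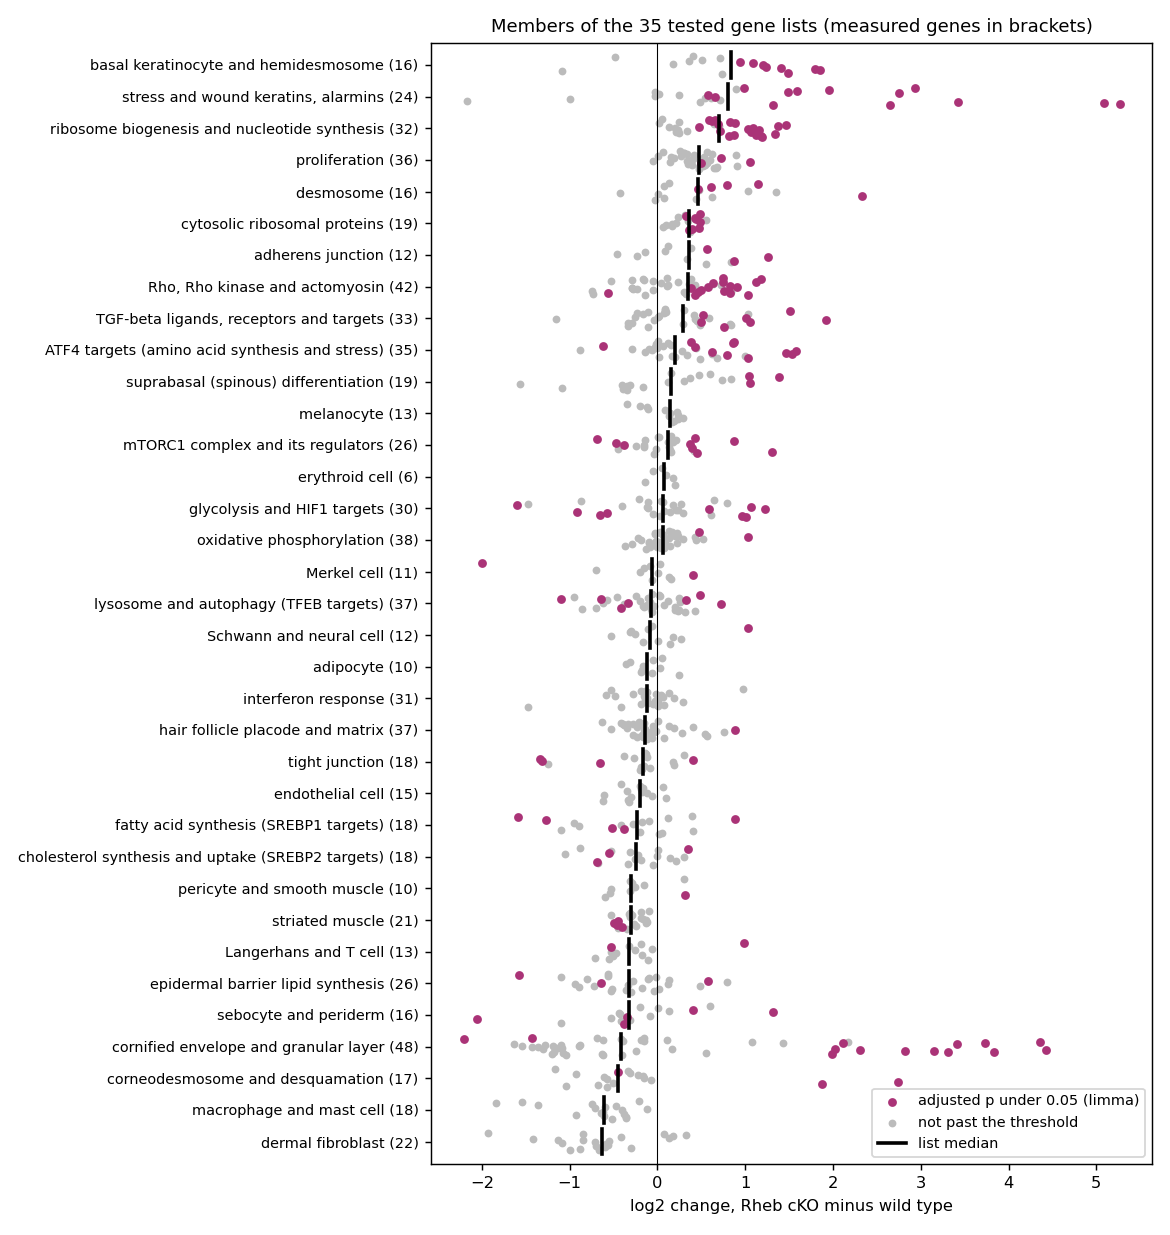
Log2 change, Rheb cKO minus wild type (x axis), of every measured member (points) of the 35 tested lists (y axis, ordered by median, member counts in brackets); coloured points passed the limma threshold and black bars are list medians. The basal, alarmin and ribosome biogenesis lists have the highest medians (0.84, 0.80 and 0.71), and the dermal fibroblast and macrophage lists the lowest (-0.63 and -0.60).

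The genes of mTORC1 itself and its regulators went both ways. Of 26 measured, 6 rose and 3 fell (7 and 4 over the list alone), and the list did not pass (median 0.12, camera adjusted p = 0.143). After control rescaling 2 rose and 5 fell (median -0.15, or 0.01 relative to all genes), and after centring on the positive controls 2 rose and 8 fell (median -0.16). Deptor, an inhibitor of the complex (log2 change 1.31 ± 0.20 SE), and Eif4ebp1, a translation repressor that mTORC1 phosphorylates (0.87 ± 0.11 SE), rose. Sesn1, a leucine sensor (-0.69 ± 0.10 SE), and Lamtor4, of the lysosomal anchor of the complex (-0.47 ± 0.08 SE), fell, and Lamtor2 of the same anchor, named after its values were seen, fell too. The kinase gene Mtor was at 6.35 in wild type and 6.30 in Rheb cKO (limma adjusted p = 0.780), and Rptor, the scaffold subunit gene, rose 1.36-fold. Without Rheb cKO replicate 6, and likewise without wild type replicate 3, 1 member of the list rose and 0 fell.

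Ribosome genes were tested as 2 lists. Of 32 genes of ribosome biogenesis and nucleotide synthesis 21 rose and 0 fell, and 26 rose over the list alone. Ddx21, an RNA helicase gene (log2 change 1.47 ± 0.17 SE), Nop2 (1.34 ± 0.14 SE), Rrp12 (1.15 ± 0.13 SE) and Bop1 (1.07 ± 0.10 SE), all of ribosomal RNA maturation, kept their calls without each array and under every scaling. Members of the list had a median of 0.71 (camera adjusted p = 4.65e-17, adjusted p = 0.480 with an estimated correlation), and relative to all genes 0.74, 0.65 after quantile normalization and 0.63 after control rescaling. Of 19 ribosomal protein genes 8 rose and 0 fell, by less, with Rpl10a (0.48 ± 0.08 SE), Rpsa (0.49 ± 0.10 SE), Rps14 (0.44 ± 0.09 SE) and Rpl7 (0.36 ± 0.08 SE) at the smallest p. Adjusted over the list alone 15 rose, and the list median was 0.36 (camera adjusted p = 3.52e-09, adjusted p = 0.480 with an estimated correlation). None of its calls held after rescaling to the control probesets (0 rose, list median 0.03, or 0.18 relative to all genes), though the list still passed, and 0 rose without wild type replicate 2, wild type replicate 3, Rheb cKO replicate 4 or Rheb cKO replicate 6. In the biogenesis list 5 genes rose without Rheb cKO replicate 6, and that list did not pass grouped by characteristic.

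Of 35 targets of ATF4, a transcription factor of amino acid shortage, 10 rose and 1 fell, and 14 rose and 2 fell over the list alone. The amino acid transporter genes Slc7a5 (log2 change 1.53 ± 0.18 SE) and Slc7a1 (1.47 ± 0.22 SE) and the asparagine synthetase gene Asns (1.03 ± 0.14 SE) rose with Eif4ebp1. Nupr1, a stress gene named after its values were seen, fell (-0.62 ± 0.15 SE). The list median was 0.20 (camera adjusted p = 2.17e-05, adjusted p = 0.480 with an estimated correlation), and 2 members rose without Rheb cKO replicate 6. After control rescaling the median was 0.02 (0.18 relative to all genes), and grouped by characteristic the list did not pass. Glycolysis and HIF1 target genes were divided, 5 up and 4 down of 30 (8 and 6 over the list alone, camera adjusted p = 0.225), and the list passed as higher against other genes with the GC-rich background covariate (0 rose, 0 fell) and after centring on the positive controls (4 rose, 8 fell, median -0.21). Hif1a, the oxygen-sensing factor itself (6.63 ± 0.13 in wild type and 7.63 ± 0.14 in Rheb cKO, SD), and Pkm, the pyruvate kinase gene (log2 change 1.22 ± 0.18 SE), rose. Bnip3, a mitophagy gene and HIF1 target (-1.61 ± 0.23 SE), and the hexokinase gene Hk1 (-0.66 ± 0.09 SE) fell. The others that passed, named after their values were seen, were Slc2a1, Ldha and Pfkfb3 (higher) and Pfkm and Aldoc (lower). Of 38 genes of oxidative phosphorylation 2 rose, Cycs (1.03 ± 0.11 SE) and Atp5b (0.47 ± 0.12 SE), and 0 fell (1 and 0 over the list alone, camera adjusted p = 0.0772), and the median of the list relative to all genes turned from 0.10 to -0.05 after quantile normalization and after rescaling, while the list passed as higher without Rheb cKO replicate 5, with the strain characteristic as a block and with array weights. Of 37 lysosome and autophagy genes 3 rose and 4 fell (6 and 5 over the list alone, camera adjusted p = 0.614). Npc2 (0.72 ± 0.11 SE) rose, and Map1lc3b (-0.64 ± 0.11 SE), Gabarapl1 (-1.10 ± 0.19 SE) and Ctsf (-0.42 ± 0.09 SE) fell. Sqstm1 and Fnip2 (higher) and Mcoln1 (lower) also passed and were named after their values were seen. Without wild type replicate 3, 1 glycolysis gene rose and 2 fell, and 0 lysosome genes passed, and without Rheb cKO replicate 6, 2 glycolysis genes rose and 0 fell.

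Lipid genes showed scattered falls. Of 26 genes of barrier lipid synthesis 1 rose and 2 fell (1 and 4 over the list alone). The ceramidase genes Acer1 (log2 change -1.58 ± 0.21 SE) and Asah1 (-0.65 ± 0.14 SE) fell, Sptlc2, of the first step of ceramide synthesis, rose (0.57 ± 0.09 SE), and Fa2h did not pass (-0.56 ± 0.15 SE). Of 18 cholesterol genes 1 rose and 2 fell (1 and 7 over the list alone): Srebf2, the regulator, rose (0.35 ± 0.07 SE), the enzyme genes Ebp (-0.55 ± 0.12 SE) and Mvd (-0.69 ± 0.17 SE) fell, and Mvk did not pass (-0.33 ± 0.09 SE). Of 18 fatty acid genes 1 rose and 4 fell (2 and 8 over the list alone), with falls of Gpam (-1.27 ± 0.19 SE), Pnpla3 (-1.59 ± 0.35 SE) and Elovl5 (-0.52 ± 0.12 SE) and a rise of Agpat2 (0.88 ± 0.15 SE), all in glycerolipid or fatty acid metabolism. Another that fell, named after its values were seen, was the desaturase gene Scd3, which also stands in the sebocyte list. With all arrays 0 of the 3 lists passed (camera adjusted p = 0.0772, 0.0772 and 0.0724). All 3 passed as lower with the strain characteristic as a block, after quantile normalization, median centring or control rescaling, with array weights and without wild type replicate 1, while the first 2 passed as higher grouped by characteristic and with the GC-rich background covariate. Without Rheb cKO replicate 6, and likewise without wild type replicate 3, 0 genes of the 3 lists passed.

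Of 36 proliferation genes 3 rose and 0 fell: the mitotic regulator genes Cdc20 (log2 change 1.05 ± 0.13 SE) and Plk1 (0.72 ± 0.17 SE) and the cyclin gene Ccne2 (0.50 ± 0.11 SE). Aurka did not pass (0.60 ± 0.16 SE), and 8 rose over the list alone. Members of the list had a median of 0.48 (camera adjusted p = 1.66e-09, adjusted p = 0.596 with an estimated correlation), and between 1 and 21 members rose when single arrays were left out, 21 without wild type replicate 1 and 1 or 2 without each of the others. After control rescaling the median was 0.22 (0.38 relative to all genes), and the list did not pass with the GC-rich background covariate or grouped by characteristic. Of 31 interferon response genes 0 passed in either direction, with limma or over the list alone, and 6 had an unadjusted p under 0.05. The nearest were Bst2 (-0.58 ± 0.15 SE), Irf7 (-1.48 ± 0.40 SE), Ifitm3 (0.98 ± 0.27 SE) and Tap1 (-0.52 ± 0.19 SE), and camera gave an adjusted p of 0.214, but the list passed as lower without wild type replicate 2 or 3, without both arrays with conflicting labels, grouped by characteristic and with the GC-rich background covariate. Of 37 hair follicle genes 1 rose, Foxn1 (0.88 ± 0.19 SE), and 0 fell (0 and 0 over the list alone, camera adjusted p = 0.453). Dlx3, S100a3 and Sox9 did not pass, and 0 hair follicle genes passed when any array other than wild type replicate 1 was left out. Of 16 sebocyte and periderm genes 2 rose, Krt17 (1.32 ± 0.20 SE) and Krt18 (0.40 ± 0.09 SE), and 3 fell, Scd3, the wax synthase gene Awat1 (-2.06 ± 0.35 SE) and the lipid droplet gene Plin2 (-0.34 ± 0.08 SE). Over that list alone 2 rose and 4 fell (camera adjusted p = 0.251), and without Rheb cKO replicate 6 or wild type replicate 3 none of its calls held (0 rose, 0 fell).

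Markers of cells outside the keratinocyte lineage were tested for RNA of other cells. Of 21 striated muscle markers 0 rose and 4 fell (0 and 7 over the list alone), by similar small amounts: Ckm (log2 change -0.40 ± 0.07 SE), Myh8 (-0.46 ± 0.09 SE), Tnnc2 (-0.45 ± 0.10 SE) and Mylpf (-0.50 ± 0.11 SE). Without wild type replicate 2, wild type replicate 3, Rheb cKO replicate 4 or Rheb cKO replicate 6, 0 of them passed. This list was lower (camera adjusted p = 7.04e-06, adjusted p = 0.596 with an estimated correlation). The macrophage and mast cell list was lower too (median -0.60, camera adjusted p = 0.000231, adjusted p = 0.508 with an estimated correlation), with 0 of 18 markers past the limma threshold (8 at an unadjusted p under 0.05) and C1qb the nearest (-0.92 ± 0.23 SE). Of 13 Langerhans and T cell markers 1 rose, Zbtb16 (0.98 ± 0.18 SE), and 1 fell, Trgv5 (-0.53 ± 0.11 SE), the receptor variable gene of the resident epidermal T cells (1 and 7 over the list alone), and 0 passed without Rheb cKO replicate 4, Rheb cKO replicate 6 or wild type replicate 3. The list was lower (camera adjusted p = 0.00526, adjusted p = 0.585 with an estimated correlation). With limma 0 of 22 dermal fibroblast markers passed (2 at an unadjusted p under 0.05, camera adjusted p = 0.0772), and their median of -0.63 shrank to -0.09 without wild type replicate 2, the array in which they stood highest.

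The remaining marker lists did not pass with all arrays; the endothelial and the fibroblast list passed as lower after median centring and without wild type replicate 1 or 3, among other fits, and the melanocyte list grouped by characteristic and with the GC-rich background covariate. With limma 0 of 15 endothelial markers passed (1 at an unadjusted p under 0.05, camera adjusted p = 0.0862), 0 of 13 melanocyte markers (1 unadjusted, 0.564), 0 of 6 erythroid markers (0 unadjusted, 0.764) and 0 of 10 adipocyte markers (0 unadjusted, 0.292). Among 10 pericyte and smooth muscle markers Cspg4 rose (log2 change 0.31 ± 0.07 SE, camera adjusted p of the list 0.564). Among 12 Schwann and neural markers Tubb3, a tubulin gene, rose (1.03 ± 0.11 SE, camera adjusted p of the list 0.817, higher, with a median of -0.09). Among 11 Merkel cell markers Krt18 rose and Chga, the chromogranin A gene, fell (-2.00 ± 0.46 SE, camera adjusted p of the list 0.820). Single markers cannot show which cells carried the change.

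The list tests have a limit of their own. With the preset correlation 13 of 35 lists passed, 10 higher and 3 lower, but the other splits of the 6 arrays into 3 and 3 gave between 12 and 17 lists. With estimated correlations 0 lists passed, with fry 1 did, and 22 lists had medians beyond random lists of matched expression.

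The arrays also differed in ways that run along the groups. The gap between the medians of the positive and the negative control probesets was 3.77 ± 0.03 in wild type and 3.95 ± 0.04 in Rheb cKO (log2, SD, n = 3 each). The mean of the background probesets with 16 to 25 G or C bases was 5.66 ± 0.19 and 5.33 ± 0.07. Neither measure overlapped between the groups, and with the background as a covariate 27 genes were higher and 7 lower. List medians with this covariate were 0.27 for the basal list, 1.73 for the alarmins, 0.45 for ribosome biogenesis, 0.25 for the desmosome, 0.09 for Rho and 0.02 for proliferation. Tested among all probesets, 43 of the 1324 positive controls were called higher and 11 lower in Rheb cKO. Of 5222 negative controls 39 were called higher and 14 lower, and of 155 spike-in probesets 0. What the positive and negative controls target was not analysed here, so their gap may also carry a change in the cells. Dermal RNA was uneven within the wild type group. The fibroblast marker median was 6.53 in wild type replicate 2 and between 5.01 and 5.19 in the other arrays, and Col1a1 was at 8.95 there against 6.47 to 7.02. Sex was mixed in both groups. Wild type replicate 3 and Rheb cKO replicate 4, the arrays with the conflicting labels, had low Xist (3.37 and below) and raised Y-linked genes (means 4.88 and 4.89), as in males, and the other 4 arrays had Xist between 9.20 and 9.84. Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty did not pass the limma test.

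**Figure D4:**
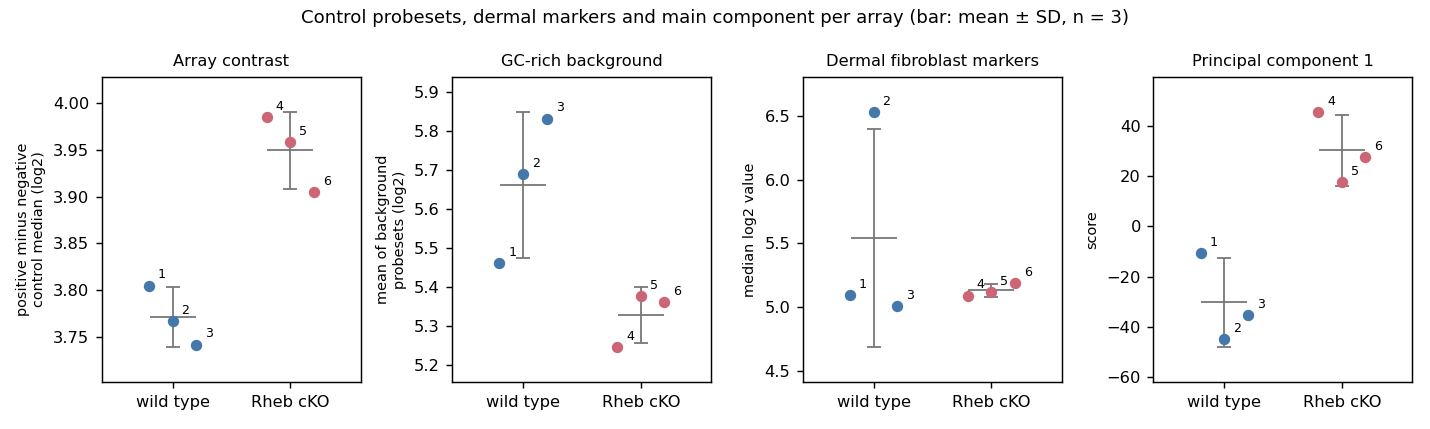
Control contrast and GC-rich background (log2), median of dermal fibroblast markers (log2) and principal component 1 score (69.7% of the variance) in the 3 wild type and 3 Rheb cKO arrays (x axis); points are arrays numbered by replicate, bars are mean and SD. Contrast, background and component 1 separate the groups, and the fibroblast panel shows wild type replicate 2 apart at 6.53.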

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

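The tests of GC-rich background, of array contrast by direction and as a whole cause, of basal-layer RNA and of gene counts over other splits were chosen after the results were seen, as were the bounds for the planned grouping by characteristic, and the control rescaling after the array controls were seen.

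Among 33142 probesets that carry no gene symbol and are not controls, 312 passed the limma threshold when all probesets were tested together, 179 higher and 133 lower in Rheb cKO. They are pointed out because the gene comparison leaves them out. TC0300002395.mm.1 was higher (log2 change 4.82), as was TC1500001079.mm.1 (3.21), and TC0600001523.mm.1 (-1.78) and TC1500001208.mm.1 (-1.79) were lower. What these probesets measure was not analysed here.

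The difference between the titled groups covered 2888 genes, and the conflicting labels raise the question whether the titles are right. Grouped by the genotype characteristic, limma called 0 genes (470 at an unadjusted p under 0.05), and each array correlated best with an array of its own titled group. Neither decides between the labels, because array contrast and GC-rich background also separate the titled groups. Rheb was at 5.934 in wild type replicate 3, above every array titled Rheb cKO. In Rheb cKO replicate 4 it was at 5.515, below every array titled wild type. On this 1 gene the values argue against 2 wrong titles. The margin of the correlations was narrow for wild type replicate 1, whose labels do not conflict. Its Pearson r was 0.986 with wild type replicate 3, 0.9856 with Rheb cKO replicate 5 and 0.9825 with wild type replicate 2. Rescaling to equal control contrast kept 56.3% of the called genes, over the bound of 50% set before, which argues against contrast as the cause of all calls, but that bound pooled directions: 97.4% of the falls stayed called, their median change at 130% of its size, and 36.1% of the rises, at 61.1%, so for the rises contrast cannot be told apart from the genotype (the rescaling moved the median of all genes from -0.04 to -0.16, which favours falls). The GC-rich background cannot be told apart from the genotype: with it as a covariate the median change of the called genes was 68.1% of its size, the sign held for 100% of them (65.8% of all genes), the standard errors were 1.55 times as large and 1% stayed called, and which of these ended the calls was not separated. With 10 splits of the 6 arrays no share under 0.05 can be reached: 1 split, the real one, gave 1935 higher and 1 split 953 lower genes, against 0 in the best of the others for each, while 9 splits gave at least the real 13 lists and the highest other gave 17. At an unadjusted p under 0.05 the real split gave 7739 genes and the others between 225 and 4390. Each of the others mixes the titled groups, which widens the spread within its sides, so their 0 adjusted calls decide little.

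The alarmin and stress keratin rise may come from keratinocytes or from cells that entered the skin. Neutrophil genes other than S100a8 and S100a9 had a median log2 change of -0.055 (17 measured, 0 past the limma threshold). At an unadjusted p under 0.05 there were 3, all higher: Retnlg by 0.55 ± 0.14 SE, Mmp9 by 0.30 ± 0.10 SE and Cxcr2 by 0.28 ± 0.11 SE. Among all 30176 genes 7739 reached that level. Camp was at 3.96 and 3.84, Ngp at 2.71 and 2.67 and Ltf at 3.34 and 3.28 in wild type and Rheb cKO. These values argue against neutrophils rich in these transcripts as the source of the rise. The list had a median level of 3.41, near the floor of the array. Fewer neutrophils, or neutrophils poor in most of these transcripts, therefore stay open. Dermal RNA in wild type replicate 2 is argued against as well, because without that array the list median was 127% of its value. Array contrast as the whole cause is argued against by the 84.6% of called members that stayed called after rescaling. A part played by contrast stays open, since the list median was then 72.1% of its value, between the bounds set for either answer, and the genotype stays open as the biological explanation.

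The ribosome biogenesis rise may reflect the genotype, array contrast, GC-rich background or a larger share of basal cells. After rescaling 71.4% of the called members stayed called, which argues against contrast as the whole cause, and the median was 67.4% of its value, which leaves a part open. With the GC-rich background as a covariate the list median was 0.45 against 0.71 without it, so that background stays open too. A larger share of basal-layer RNA would lower no basal marker, and 6.25% of them, Krt15 alone, were lower by more than 2 SE, too few to decide, so it stays open. So does a change of the basal cells themselves.

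The region around Rheb held no excess of called genes: 19 of 195 placed genes within 10 Mb were called against 2345 of 22014 elsewhere, a ratio of shares of 0.915 (Fisher's exact test, two-sided, p = 0.815).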

How the results depend on the processing

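The control rescaling, the centring on positive controls and the GC-rich background covariate were chosen after the data were seen, and all other alternatives before. No paired analysis was possible because no label records which embryos shared a litter and the groups share no replicate numbers. Where a value below departs from the one reported, the cause was not tested, unless fewer arrays or more tests are part of the alternative. The range of the arrays limits dim genes, whose folds the background compresses.

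Grouped by characteristic, 0 genes were higher and 0 lower, and Rheb changed by -0.24. Among named genes that had passed by title, log2 changes of the opposite sign were 0.10 for Slurp2, 0.14 for Serpinb3c, 0.11 for Cgn, 0.078 for Ocln, 0.087 for Mvd, 0.16 for Pnpla3, 0.013 for Mylpf and 0.26 for Chga. Lists are named as turned only where they passed by title or under the alternative. Those that turned higher under this grouping, with camera adjusted p, were desquamation (0.000834), barrier lipid (2.81e-07) and cholesterol (0.00623). Those that turned lower were ATF4 (0.765), proliferation (0.113), TGF-beta (0.283), Rho (0.407) and melanocyte (0.0136). Another 6 lists changed direction without passing in either fit. With the GC-rich background covariate 27 genes were higher and 7 lower, and Rheb changed by -0.78 without passing. Desquamation (camera adjusted p = 0.00112), barrier lipid (0.000374) and cholesterol (0.0296) then turned higher, and proliferation (0.994) and melanocyte (0.00705) lower. With this covariate 4 further lists changed direction without passing in either fit. Against random matched lists the cornified list was lower (adjusted p = 0.000583).

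Leaving out single arrays gave 290 to 3207 higher and 127 to 1706 lower genes, 13 to 19 lists and Rheb changes of -0.60 to -0.42. Without both conflicting arrays 44 were higher and 10 lower, and Rheb changed by -0.57 without passing. Higher and lower genes numbered 1163 and 521 with the Y-linked covariate, 1133 and 528 over all probesets, 1 and 2 without moderation, 3588 and 2205 with array weights, 705 and 1764 after control rescaling, and 1040 and 8741 after centring on positive controls. Rheb kept its change of -0.52 but did not pass over all probesets or without moderation. At an adjusted p under 0.1 the counts were 3102 and 1792, at 1.5-fold or more 1120 and 517, and at an unadjusted p under 0.05 4383 and 3356. Lists past the threshold numbered 0 with estimated correlations, 1 with fry and 22 against random lists.

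Of the 12 largest rises 4 kept their calls with the GC-rich background covariate and 10 without both conflicting arrays, and of the 12 largest falls 0 and 5. There were 173 named genes, and Rheb is left out of the counts that follow. Of the others, 134 kept direction and side of the threshold after control rescaling, 152 after quantile normalization and 162 after median centring. With the background covariate 57 did, without moderation 61, and between 97 and 151 when single arrays were left out.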

Other observations

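The tests here were chosen after the gene results were seen.

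Further genes, chosen after their values were seen, moved in Rheb cKO. Of 11 measured Skint genes, a family expressed in keratinocytes, 10 fell, with a family median log2 change of -1.63. Of 10 measured ligands of the epidermal growth factor receptor family, 4 rose, 2 fell and 4 did not pass, among the last Ereg (log2 change 0.90 ± 0.62 SE). Their median of 0.41 was at percentile 99.9 among random lists matched on mean level, while camera did not call the set. This percentile does not show a common shift. The family was chosen after its values were seen, and 22 of the 35 fixed lists passed the random-list test. Its log2 changes ran from -3.42 (Btc) to 2.93 (Epgn). Tgfa, Hbegf, Epgn and Ereg are also in the alarmin list. Btc was 10.7-fold lower and Nrg4 fell (-0.38 ± 0.08 SE), while Epgn (log2 change 2.93 ± 0.22 SE), Nrg1 (2.91 ± 0.23 SE), Hbegf (1.96 ± 0.14 SE) and Tgfa (0.99 ± 0.23 SE) rose, as did the receptor gene Egfr (0.79 ± 0.15 SE). The prostaglandin synthase gene Ptgs2 (3.28 ± 0.44 SE), the immediate early gene Arc (2.97 ± 0.12 SE), the cytokine genes Il24 (2.55 ± 0.10 SE) and Il33 (1.98 ± 0.17 SE) and the matrix protease gene Mmp3 (2.64 ± 0.11 SE) rose too. Among the falls, with no test of enzyme genes as a group, were Cyp2g1 (-2.39 ± 0.33 SE), Adh6b (-1.71 ± 0.32 SE), Cyp2f2 (-1.49 ± 0.24 SE) and Cyp2b10 (-1.21 ± 0.25 SE). All of these except Ereg passed the limma threshold.

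Several genes that the kinase ERK induces were among the rises, with Dusp6 at a log2 change of 2.63, Dusp7 at 1.80, Etv4 at 1.45, Fosl1 at 1.38 and Egr1 at 1.04. The hypothesis that ERK signalling may be higher in Rheb cKO epidermis was tested on a separate list of ERK feedback and response genes whose values had not been looked at. Of 19 measured 7 rose and 0 fell, with a median log2 change of 0.49, at percentile 100 among 10000 random lists matched on mean level (camera p = 7.76e-06, or p = 0.00886 with an estimated correlation, neither adjusted). The random-list test and the preset correlation are lenient here: 22 of the 35 fixed lists passed the first, and other splits of the arrays gave 12 to 17 lists with the second. Of the members that did not pass, Spry1 was lower in every Rheb cKO array (-0.35 ± 0.09 SE), and Lif (-0.17), Maff (-0.04), Dusp5 (0.06) and Dusp4 (0.07) changed little. Such genes respond to other signals as well, and phosphorylated ERK was not measured. Part of the shift may come from the array contrast and the GC-rich background, which differ between the groups.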
